A study of Homo sapiens with 18 samples.

How the data were processed

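Droplet single-cell RNA sequencing was carried out on live cells from 9 head and neck squamous cell carcinomas, 5 primary tumours and 4 lymph node metastases from 7 patients. Each tumour was divided into a fraction dissociated with enzymes and a fraction dissociated mechanically, and the 2 fractions were processed as separate 10x libraries, which gave 18 libraries. For 6 tumours the cells were also stained with oligonucleotide-tagged antibodies (AbSeq), in panels of 36, 44 and 50 antibodies, each panel serving 1 primary tumour and 1 metastasis. Both libraries of primary tumours 1 and 3 and of metastasis 2 had no antibody panel. Tumours are numbered here within their site in the order of the series.

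The authors deposited, for each library, a matrix of counts of unique molecular identifiers (UMIs) per gene and barcode, with 33538 genes. Cell Ranger 3.0.2 and the genome build GRCh38 are named in the submitters' processing notes. The settings of the alignment, the use of strand in counting and the way barcodes were called as cells are not given in the sources used here. The antibody tables hold counts of molecules per antibody and barcode, as the authors deposited them, and their barcodes were joined to those of the RNA matrix of the same library. All values used here are raw counts. Total UMI counts per library ranged from 1202141 to 40710402. The median UMI count per kept cell ranged from 2088 to 5275 over libraries, with a median over libraries of 2546.5 for the enzymatic and 2759 for the mechanical fraction. The number of kept cells ranged from 204 to 11123 per library.

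Barcodes with at least 200 detected genes and at most 20% of UMIs from mitochondrial genes were used, which removed 4333 of 54358 barcodes and between 0.270% and 44.9% of a library. Doublet scores were computed per library with the scrublet implementation of scanpy. Its automatic threshold marked 747 of the 50025 remaining cells, so the cells with the highest scores were removed at a fixed rate of 0.8% per 1000 cells of the library, which took out 2192 cells and left 47833. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes over libraries were taken, without immunoglobulin and T cell receptor segments, mitochondrial and ribosomal protein genes. After 30 principal components and 15 nearest neighbours, cells were clustered with the Leiden algorithm at resolution 1 with a fixed seed and without any batch integration, which gave 30 clusters. A cluster was named "X-like" from marker genes fixed beforehand, when at least 3 and at least 0.5 of the markers were detected in 10% or more of its cells and the score of the next lineage was at most 0.55 of its own score. A cluster also stayed unnamed when another class had more markers among its 10 leading genes, or when its depth was low and none of them was a marker of its own class. These naming thresholds and the fixed doublet rate were set after the cells had been seen. Naming left 2 clusters with 857 cells unnamed because they carried markers of 2 lineages. Unnamed cells made up 6.44% of the enzymatic libraries of primary tumours, 0.559% and 0.196% of the enzymatic and mechanical libraries of metastases, and 0.013% of the mechanical libraries of primary tumours. In the enzymatic library of primary tumour 1 they were 36.9% of cells, which lowers the shares of the named classes there.

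Shares are percentages of all kept cells of a library, and classes with at least 1% of all cells were tested. The fractions were compared with an exact two-sided sign-flip test over all 512 flips of the 9 tumour pairs. The sites were compared with an exact two-sided permutation test over the 126 assignments of 4 of 9 tumours, after averaging the 2 fractions of a tumour. For expression, counts were summed over the cells of a class in each library (fraction) or tumour (site), where at least 20 cells were present. Sums per tumour added both fractions as they were, so that the fractions weighed unequally between tumours. Kept cells of all classes were 3290 enzymatic and 204 mechanical in metastasis 1, and 2460 and 6304 in metastasis 4. Site values of genes that differ between the fractions can carry this imbalance, and single fractions were fitted as an alternative. Sums were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM normalization, filterByExpr), with the tumour as a block for the fraction, no covariate for the site, and an interaction term for whether the fraction difference differed between sites. Antibody counts were summed and tested in the same way over the 16 antibodies shared by all 3 panels, with the panel as a block for the site, so that their fold changes are relative to the other shared antibodies. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Of the prepared lists, 25 gene lists and 17 marker lists with at least 5 measured genes were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, and again with the correlation estimated from the data. Gene list members were also counted with p-values adjusted over the list alone.

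The numbers of the 2 fractions pair them by tumour, since they are parts of 1 specimen. In T-like cells, the deviations of the 2 fractions of a tumour from their group means correlated at 0.351 to 0.788 (median 0.578, 3197 genes). Among the mechanical libraries of its site, the enzymatic library correlated best with its own partner in 9 of 9 tumours. Libraries of the other site were not compared. Of 32 pairs of libraries within a group, 0 were identical, and the lowest chi-square per degree of freedom was 25.9, so that all were counted as separate samples. The tumours are separate specimens, but 2 patients gave both a primary tumour and a metastasis (primary tumour 2 with metastasis 1, and primary tumour 3 with metastasis 2). Tests of the site treated these as independent, and a fit with the patient as a random block is given as an alternative.

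Genes were named by a rule. In each class these were the 5 largest positive and 5 largest negative log2 fold changes among genes with an adjusted p under 0.05, a mean log CPM of at least 5 and the same sign in at least 0.75 of the tumour pairs, or groups that did not overlap for the site. Where no gene passed, the 3 smallest p-values were taken, as values only, and up to 4 members with the smallest p were added from each list that passed or belonged to the class. Antibodies were named when they passed, together with those against CD3, CD4, CD8, CD45 and EPCAM. Some genes and antibodies that the rule selected are not reported here. Genes of the interaction and of the classes added later lay outside the rule. The grouping, tests, lists, markers, naming rule for genes and most alternatives were chosen before the data were examined. The exceptions were the alternatives with unnamed cells counted as T-like, without tumours with a library under 500 cells, without primary tumour 1 and metastasis 1, limma without the block and interaction fits without single tumours, and the fits of NK-like, dendritic-like and plasma-like cells. The other alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, doublets kept, a mitochondrial limit of 10%, at least 50 cells per sum, other clustering resolutions (0.5 and 2), no block, the antibody panel as covariate, single fractions and leaving out each tumour in turn.

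The expression fits were tested on simulated counts in which 200 genes were changed by a known amount, and the tests of shares on simulated values. Clustering, naming, doublet removal and the antibody tests were not simulated. Percentages refer to changed genes that passed the filter on low counts, between 156 (NK-like cells, fraction) and 197 (macrophage-like cells, interaction). In the fraction fits 100% of the 4-fold changes were found in each class. Of 2-fold changes 100% were found in T-like, 88.5% in B-like, 96.5% in macrophage-like, 96.4% in NK-like, 98.9% in dendritic-like and 77.4% in plasma-like cells. In the site fits, 2-fold and 4-fold changes were found at 19.4% and 85.4% in T-like cells, 33% and 100% in B-like cells, 18.4% and 92.4% in macrophage-like cells, 9.5% and 64% in fibroblast-like cells, and 0% and 0% in epithelial-like cells. For the interaction the shares were 44.9% and 85.4% in T-like cells and 6.1% and 64.6% in macrophage-like cells. These shares hold for the simulated spread. Real genes fitted beyond 4-fold by site in T-like cells did not pass. In the tests of shares, draws without a difference gave a p under 0.05 in 0.05 of the fraction draws and 0.055 of the site draws.

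The fraction was not tested in epithelial-like and fibroblast-like cells, since 2 tumours had at least 20 such cells in both libraries. XIST, TSIX and Y-linked genes (130 in all) were left out of all tests, and no genotype or copy number was inferred. Clone-named genes, V, D and J segments, HLA-DRB5 and GSTM1 were not named. Genes with near-identical copies, such as HSPA1A and HSPA1B, CCL3 and CCL4 with their copies, the IGHG constant genes and HLA class II genes, can share reads, so their separate values are uncertain. MT-ND6 lies on the strand opposite its neighbours, and how strand was used in counting is not known. Gene positions are from GENCODE v29 on GRCh38 (1-based). Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3.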

Results

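Live cells of 9 head and neck squamous cell carcinomas (5 primary, 4 lymph node metastases) were profiled in enzymatic and mechanical fractions. After quality filters 47833 cells in 18 libraries were analysed. Lymphocytes made up most of the cells. T-like cells were 26707 (55.8%), B-like cells 7142 (14.9%), NK-like cells 1645 (3.44%) and plasma-like cells 1353 (2.83%). Macrophage/monocyte-like cells (macrophage-like below) were 3337 (6.98%) and dendritic-like cells 2234 (4.67%). Epithelial-like cells, in which carcinoma cells were not told apart from other epithelial cells, were 2216 (4.63%) and fibroblast-like cells 949 (1.98%). Mural-like (459), endothelial-like (423), plasmacytoid-like (355) and mast-like cells (156) were each under 1% of cells and were not tested. One cluster of 730 unnamed cells came from the enzymatic library of primary tumour 1 and was led by IGHG4, ACKR1, SELE, IFNG, HSPA6 and PLVAP.

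The first comparison asked whether the 2 ways of dissociation recovered the same cells. Fibroblast-like cells were more frequent in the enzymatic fraction of 9 of 9 tumours, with 4.61% ± 6.25 of cells against 1.17% ± 2.33 (SD, n = 9), a mean difference of 3.45 percentage points. Dendritic-like cells were less frequent in the enzymatic fraction of every tumour, with 4.31% ± 2.62 against 7.56% ± 3.91, a difference of -3.25 points. Both reached the smallest p that 9 pairs allow (exact two-sided sign-flip test, p = 0.00391, adjusted p = 0.0156). The other classes did not pass, with adjusted p-values of 0.240 to 0.801 in the same exact test. T-like cells made up 48.9% ± 19.9 of enzymatic and 50.0% ± 22.4 of mechanical libraries, and B-like cells 8.01% ± 10.4 and 11.2% ± 13.1. Macrophage-like cells made up 10.4% ± 10.1 and 11.8% ± 12.2, and NK-like cells 3.06% ± 2.01 and 3.60% ± 2.64. Plasma-like cells made up 3.83% ± 3.57 and 3.03% ± 2.77, and epithelial-like cells 7.54% ± 12.9 and 8.93% ± 20.3. Without the pairing neither fibroblast-like nor dendritic-like cells passed. Without the 2 tumours that had a library under 500 cells (primary tumour 3 and metastasis 1) both classes were at the smallest p that the remaining pairs allow (adjusted p = 0.0625, exact test), with differences of 1.53 and -2.76 points. The dendritic-like difference was -0.324 points at clustering resolution 0.5 (adjusted p = 0.273) and -1.30 points at resolution 2 (adjusted p = 0.104). At resolution 2 macrophage-like cells passed with -5.16 points (adjusted p = 0.0156, exact test), but the class was made up differently there. A cluster of 1474 cells led by IL1B, CXCL8 and CXCL2 stayed unnamed, and a cluster of 961 cells was added. Its leading genes held the macrophage markers MARCO and SPP1 and the dendritic marker CLEC9A, with S100B, CPVL and MMP9. The last 3 were also among the leading genes of the dendritic-like cluster 12 at resolution 1. The line between the dendritic-like and macrophage-like classes thus depended on the resolution.

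**Figure D1:**
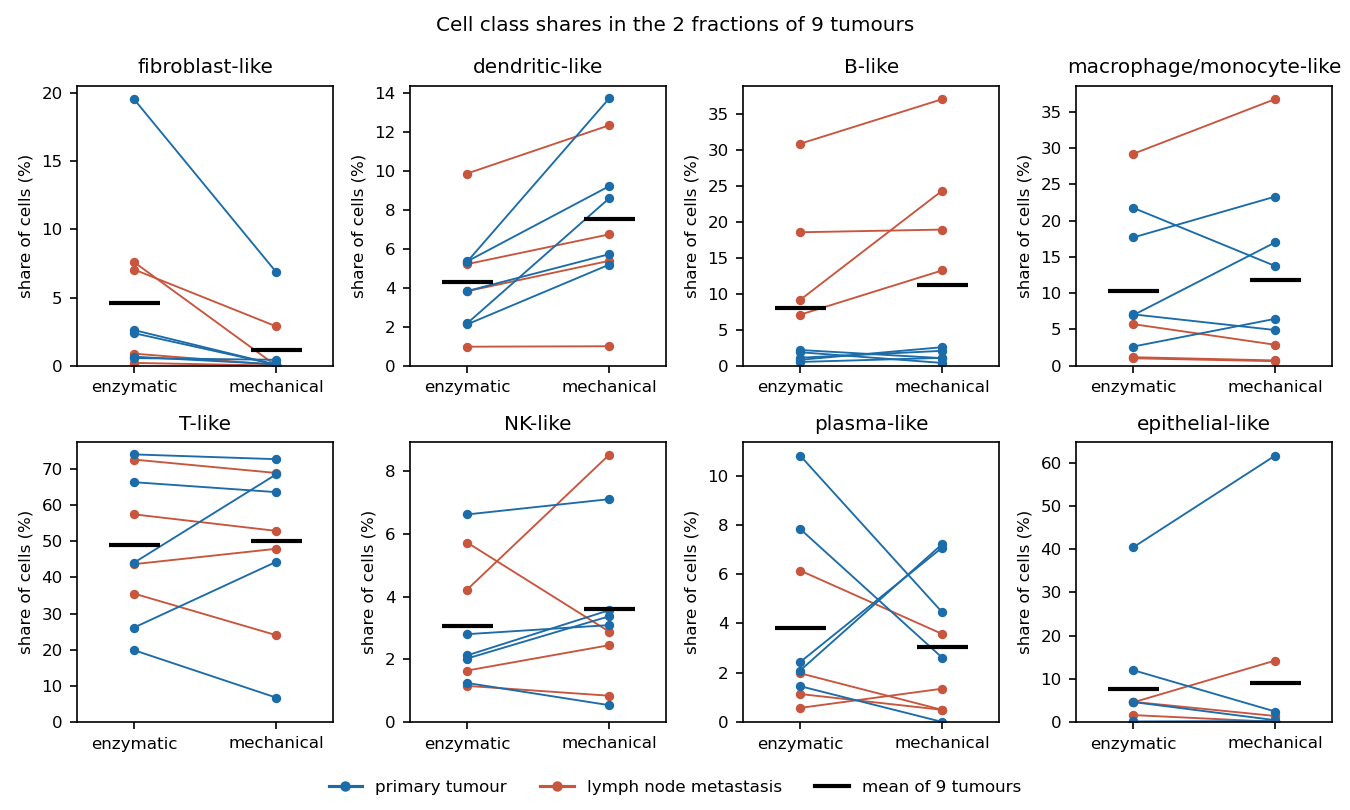
Shares of 8 cell classes (vertical axes, percent of the cells of a library) in the enzymatic and mechanical fraction of each tumour, with lines joining the fractions of 1 tumour and black bars for the means of 9 tumours. Fibroblast-like shares are higher in the enzymatic fraction and dendritic-like shares in the mechanical fraction of all 9 tumours, and B-like shares lie higher in the 4 metastases than in the 5 primary tumours.

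Expression within T-like cells differed strongly between the fractions, led by immediate early and heat shock genes. NR4A2, a nuclear receptor induced within minutes of cell activation (ENSG00000153234, chromosome 2, 156324432 to 156342348, minus strand), had 319 ± 101 CPM in the enzymatic and 12.8 ± 10.5 CPM in the mechanical fraction (SD, n = 9). This was a log2 fold change of 4.77 ± 0.21 (SE). Its paralogue NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507, plus strand) was higher by 3.65 ± 0.12, and ATF3, a stress-induced transcription factor, by 4.48 ± 0.23. Among chaperones, DNAJB1, an Hsp40 co-chaperone (ENSG00000132002, chromosome 19, 14514770 to 14529770, minus strand), had 1336 ± 715 against 70.3 ± 30.6 CPM and a log2 fold change of 4.24 ± 0.25. HSPA1B, an inducible Hsp70 (ENSG00000204388, chromosome 6, 31827735 to 31830255, plus strand), was higher by 4.92 ± 0.53. IFNG, the gene of interferon gamma (ENSG00000111537, chromosome 12, 68154768 to 68159747, minus strand), rose with them, from 65.7 ± 70.7 to 627 ± 574 CPM (log2 fold change 3.24 ± 0.17, adjusted p = 1.55e-11). All of these were higher in the enzymatic fraction of 9 of 9 tumours.

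By edgeR, 2022 of 9728 genes passed in T-like cells, 1036 higher and 986 lower in the enzymatic fraction. With size factors of DESeq2 in place of TMM, the share of higher genes among those passing was 56.3% against 51.2%. All 21 measured immediate early genes rose, also when adjusted over the list alone. Their median log2 fold change was 2.11 (camera adjusted p = 4.54e-63; adjusted p = 0.00319 with an estimated correlation). All 15 heat shock genes rose over all genes and adjusted over the list alone, among them HSPH1 (3.06 ± 0.19) and DNAJA1 (2.89 ± 0.13). Heat shock genes had a median of 2.28 (camera adjusted p = 3.54e-41; adjusted p = 0.0171 with an estimated correlation). Of 11 inflammatory monocyte genes, 10 rose over all genes and 11 adjusted over the list alone, with a median of 1.62 (camera adjusted p = 3.29e-12; adjusted p = 0.00149 with an estimated correlation). They included the cytokine TNF (2.27 ± 0.23) and CXCL2 (3.65 ± 0.32), a chemokine made mainly by myeloid and stromal cells.

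Smaller groups moved in part. Of 15 cytotoxic genes 4 rose over all genes and 4 adjusted over the list alone (median 0.12, camera adjusted p = 0.00536; adjusted p = 0.702 with an estimated correlation). These were the cytokine gene IFNG and the chemokine genes CCL4 (1.62 ± 0.21), CCL3 (1.20 ± 0.21) and CCL5, which are released on activation, and not genes of cytolytic granules. Of 12 hypoxia genes 4 rose (5 rose and 1 fell adjusted over the list alone), led by ANKRD37 (2.45 ± 0.15), a target of hypoxia-inducible factor, and PFKFB3 (1.34 ± 0.14), a regulator of glycolysis. The list had a median of 0.18 (camera adjusted p = 0.0128; adjusted p = 0.443 with an estimated correlation). Markers of epithelial cells were also higher in T-like cells of the enzymatic fraction, 5 of 5 over all genes and adjusted over the list alone. Their median was 1.69 (camera adjusted p = 0.00536; adjusted p = 0.468 with an estimated correlation). The keratins KRT14 (39.9 ± 53.5 against 3.13 ± 4.75 CPM, log2 fold change 3.37 ± 0.38) and KRT17 (2.75 ± 0.45) were higher in 8 of 9 tumours.

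The largest decreases were smaller than the increases. MT-ND6, a mitochondrially encoded subunit of respiratory complex I (ENSG00000198695, mitochondrial genome, 14149 to 14673, minus strand), fell by 1.45 ± 0.13 on the log2 scale, from 93.3 ± 36.8 CPM in the mechanical to 36.0 ± 24.2 CPM in the enzymatic fraction. The other mitochondrial transcripts did not fall with it, since 12 of 13 lay above 0 in T-like and B-like cells and 11 of 13 in macrophage-like cells, and 4 rose over all genes in T-like cells. SLC25A45, a mitochondrial carrier, fell by 1.34 ± 0.11, NHLRC3 fell by 1.15 ± 0.13, ANKRD49 fell by 0.99 ± 0.13 and GIMAP6, a GTPase of lymphocytes, fell by 0.86 ± 0.12, each in 9 of 9 tumours. The T-like clusters of the fractions differed. Clusters 2, 4, 6, 14, 15 and 17 were mostly enzymatic, and clusters 0, 3, 7, 8 and 24 mostly mechanical. Of these, 63.1% of cluster 15 came from the enzymatic library of primary tumour 5 and 93.8% of cluster 24 from the mechanical library of primary tumour 1. Cluster 17, led by IFNG, HSPA1B, HSPA6, TNF and DNAJB1, held 16.5% of T-like cells of the enzymatic and 0.181% of the mechanical libraries of primary tumours, and 63.2% of its cells came from the enzymatic library of primary tumour 1. Without primary tumour 1 and metastasis 1, 1682 genes passed, and without the tumour block 780 passed.

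In B-like cells the same groups led. NR4A2 had 731 ± 313 CPM in the enzymatic and 11.6 ± 21.2 CPM in the mechanical fraction of 5 tumours, a log2 fold change of 7.03 ± 0.38 (SE), and NR4A1 was higher by 5.75 ± 0.30. FOS, a component of the AP-1 transcription factor, was higher by 4.90 ± 0.43, and TNFSF9, a co-stimulatory ligand, by 4.93 ± 0.37. DNAJB1 was higher by 4.66 ± 0.25, and each of these genes was higher in 5 of 5 tumours (4 metastases and primary tumour 5). By edgeR, 524 of 5292 genes passed, 413 higher and 111 lower in the enzymatic fraction. All 17 immediate early genes rose, also adjusted over the list alone, with a median of 3.01 (camera adjusted p = 1.31e-64; adjusted p = 0.0768 with an estimated correlation). Among them were ZFP36, which destabilises cytokine mRNA (2.92 ± 0.23), and SOCS3, an inhibitor of cytokine signalling (3.73 ± 0.30). All 11 heat shock genes rose, also adjusted over the list alone, with a median of 2.19 (camera adjusted p = 2.90e-39; adjusted p = 0.0768 with an estimated correlation), including HSPH1 (3.02 ± 0.21).

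Of 5 inflammatory monocyte genes in B-like cells, 3 rose over all genes and 5 adjusted over the list alone (CCL4 1.72 ± 0.21, TNF 1.68 ± 0.26 and the myeloid gene S100A9 1.51 ± 0.34 passed over all genes). That list had a median of 1.51 (camera adjusted p = 0.000166; adjusted p = 0.125 with an estimated correlation). Of 13 type I interferon genes, IFITM1 (-1.0 ± 0.20) and OAS1 (-0.93 ± 0.24), both antiviral effectors, fell over all genes and adjusted over the list alone. Interferon genes had a median of -0.49 (camera adjusted p = 0.0112; adjusted p = 0.693 with an estimated correlation). MT-ND6 fell by 1.19 ± 0.23 and CYTH4 fell by 1.18 ± 0.22 on the log2 scale. POLD4, a DNA polymerase subunit, fell by 1.11 ± 0.23 and SLC25A45 fell by 1.09 ± 0.27. The long non-coding RNA LINC01116 (-1.24 ± 0.34, edgeR adjusted p = 0.0148) was lower in 4 of 5 tumours and did not pass by DESeq2 or without metastasis 1 or metastasis 3. Cluster 1 held 82.4% and 89.0% of B-like cells in the enzymatic libraries of metastases and primary tumours and 2.54% and 2.04% in the mechanical ones. Cluster 5 held 90.3% and 91.8% in the mechanical libraries. The count of passing genes was 312 without metastasis 4, and 276 without the tumour block.

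Macrophage-like cells of the enzymatic fraction carried high levels of chemokines and cytokines. CXCL2, a neutrophil chemokine (ENSG00000081041, chromosome 4, 74097035 to 74099293, minus strand), had 2848 ± 1545 against 198 ± 294 CPM (SD, n = 9) and was higher by 4.78 ± 0.59 on the log2 scale (SE). TNF (ENSG00000232810, chromosome 6, 31575567 to 31578336, plus strand) rose by 3.63 ± 0.27, from 10.9 ± 15.9 to 146 ± 114 CPM. IL1B, the gene of interleukin 1 beta, had 2449 ± 1858 against 510 ± 846 CPM and was higher by 3.11 ± 0.46. Other chemokine genes rose too, CCL20 by 4.16 ± 0.52, CXCL3 by 4.0 ± 0.63, CCL3 by 3.04 ± 0.46 and CCL4 by 2.33 ± 0.51, each in 9 of 9 tumours. By edgeR, 462 of 4394 genes passed, 343 higher and 119 lower in the enzymatic fraction. Of 18 inflammatory monocyte genes 13 rose and 2 fell over all genes, and 13 rose and 4 fell adjusted over the list alone (median 2.53, camera adjusted p = 3.40e-10; adjusted p = 0.150 with an estimated correlation). The 2 that fell, FCN1 and VCAN, are expressed by circulating monocytes.

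Immediate early and heat shock genes rose in macrophage-like cells too. Of 20 immediate early genes 17 rose over all genes, and 19 rose and 1 fell adjusted over the list alone (median 1.34, camera adjusted p = 1.21e-24; adjusted p = 0.0780 with an estimated correlation). Among them were DUSP2, a phosphatase of MAP kinases (3.96 ± 0.34), GEM (4.04 ± 0.47), a small GTPase, IER3 (3.48 ± 0.31) and NFKBIA (2.44 ± 0.25), the inhibitor of NF-kappa-B. Of 14 heat shock genes 11 rose over all genes and 13 adjusted over the list alone (median 1.35, camera adjusted p = 8.24e-16; adjusted p = 0.0780 with an estimated correlation). DNAJB1 and HSPA1A were both higher by 2.99 ± 0.38. Of 10 MHC class II genes, which present antigen to CD4 T cells, 6 rose over all genes and 9 adjusted over the list alone, by small amounts such as 0.53 ± 0.13 for HLA-DRB1 and 0.50 ± 0.13 for CD74. MHC class II genes had a median of 0.45 (camera adjusted p = 0.00163; adjusted p = 0.344 with an estimated correlation).

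Of 17 tumour-associated macrophage genes 4 rose, 9 rising and 2 falling adjusted over the list alone (median 0.61, camera adjusted p = 0.0231; adjusted p = 0.344 with an estimated correlation). Examples were the folate receptor FOLR2 (0.96 ± 0.22) and the complement gene C1QC (0.72 ± 0.19, edgeR adjusted p = 0.0231), which did not pass without metastasis 1, primary tumour 3 or primary tumour 5. Of 6 inflammatory fibroblast genes 3 rose over all genes and 3 adjusted over the list alone (CXCL2, CXCL1 and IL6, the last by 1.71 ± 0.36). Of 7 cytotoxic genes 3 rose (CCL3, CCL4 and CST7) and 4 adjusted over the list alone. These lists had medians of 0.77 and 0.75 (camera adjusted p = 0.0231 for both; adjusted p = 0.150 for both with an estimated correlation). RIPOR2 (-1.50 ± 0.21), SPN, a sialoglycoprotein of leukocytes (-1.43 ± 0.22) and MT-ND6 (-1.36 ± 0.21) were lower. RETN, the gene of resistin (-1.33 ± 0.40, edgeR adjusted p = 0.0434), was lower in 7 of 9 tumours. Cluster 9, led by IL1B, FCN1, CXCL3 and CXCL8, held 48.4% and 64.5% of macrophage-like cells in the enzymatic libraries of metastases and primary tumours and 88.8% and 82.3% in the mechanical ones. Cluster 16, led by SELENOP, C1QA and FOLR2, held the rest. Without the tumour block 191 genes passed, and with no filter on low counts 857. With at least 50 cells per sum 379 passed, 274 of them among the 462.

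Of 3526 genes tested in all 3 classes, 186 were higher in the enzymatic fraction in T-like, B-like and macrophage-like cells alike, against 3.97 expected for independent lists, and 8 were lower in all of them, against 0.09. NR4A1, NR4A2 and DNAJB1 were among the strongly raised genes of more than 1 class.

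Surface proteins were compared between the fractions with the 16 antibodies shared by all panels. The antibody against CD185 detects the chemokine receptor CXCR5 (ENSG00000160683, chromosome 11, 118883766 to 118897799, plus strand). It had 1.60 ± 1.01 molecules per B-like cell in the enzymatic and 155 ± 180 in the mechanical fraction (SD, n = 4). The log2 fold change was -6.18 ± 0.61 (edgeR adjusted p = 6.13e-05, lower in 4 of 4 tumours). CXCR5 RNA in the same class was higher in the enzymatic fraction by 1.03 ± 0.25 in 5 of 5 tumours (edgeR adjusted p = 0.0036). In T-like cells CD185 was lower too, with 1.39 ± 0.95 against 13.9 ± 12.7 molecules per cell (n = 6) and a log2 fold change of -2.01 ± 0.61 (edgeR adjusted p = 0.0318, lower in 6 of 6 tumours). CD4 antibody in T-like cells had 304 ± 256 against 1692 ± 1359 molecules per cell and was lower in 6 of 6 tumours but did not pass (-1.36 ± 0.48, edgeR adjusted p = 0.0578). CD3 (676 ± 744 against 1202 ± 979) and CD7 (345 ± 260 against 949 ± 818) also had fewer molecules per T-like cell, by smaller factors.

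Relative to the other antibodies, CD274 (PD-L1, the ligand of PD-1) was higher in the enzymatic fraction of T-like cells (1.34 ± 0.36, edgeR adjusted p = 0.0212) and B-like cells (1.24 ± 0.34, edgeR adjusted p = 0.0171). It had 77.4 ± 47.7 against 70.1 ± 63.8 molecules per T-like cell and was lower per cell in 2 of 6 tumours, so that in T-like cells the increase rests mostly on the scaling to the other antibodies. B-like cells also had higher CD278 (the co-stimulatory receptor ICOS, 0.87 ± 0.16), CD33 (a sialic acid-binding receptor of myeloid cells, 0.63 ± 0.17) and CD8 (1.47 ± 0.38). CD8 was higher in macrophage-like cells too (1.29 ± 0.31, edgeR adjusted p = 0.0105). The antibodies against CD3 (0.26 ± 0.41, edgeR adjusted p = 0.611) and CD8 (0.65 ± 0.35, 0.181) in T-like cells and CD4 in macrophage-like cells (-0.95 ± 0.38) did not pass. In all, 2 antibodies passed in T-like, 5 in B-like and 1 in macrophage-like cells. Exact sign-flip tests could not pass with 4 pairs (smallest two-sided p 0.125) and gave 0 antibodies with 6 pairs (smallest p 0.03125), where few antibodies at that p cannot pass after adjustment. Scaling to the total of the shared antibodies left 0 in T-like and 3 in B-like cells. Within libraries, the correlation of antibody and RNA levels across cell classes, which are not independent replicates, had a median over 6 libraries of -0.352 in the enzymatic and 0.878 in the mechanical fraction for CD185. It was 0.854 and 0.915 for CD4.

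**Figure D2:**
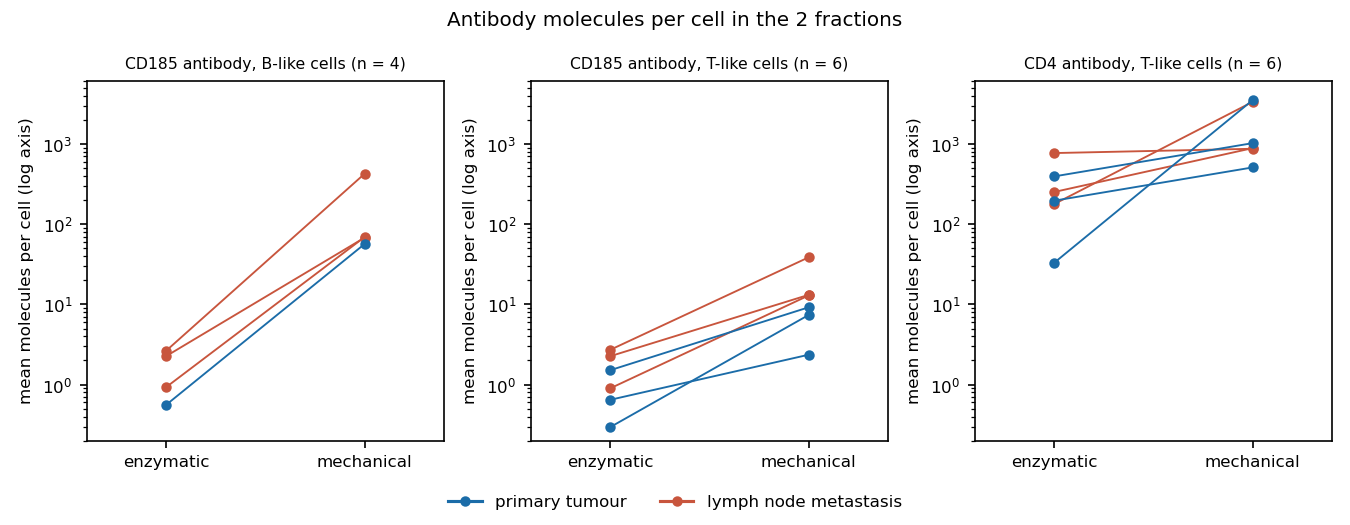
Mean antibody molecules per cell (vertical log axes) in the enzymatic and mechanical fraction, with 1 line per tumour, for CD185 in B-like cells (n = 4) and CD185 and CD4 in T-like cells (n = 6). CD185 falls in every tumour between the mechanical and the enzymatic fraction, with means of 155 and 1.60 molecules per B-like cell.

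The second comparison set lymph node metastases against primary tumours. B-like cells made up 19.9% ± 10.1 of cells in metastases (SD, n = 4) and 1.36% ± 0.384 in primary tumours (n = 5), a difference of 18.5 points with no overlap. This reached the smallest p that the design allows but did not pass after adjustment (exact two-sided permutation test, p = 0.00794, adjusted p = 0.0635). The metastasis exceeded the primary tumour of the same patient by 9.03 and 15.1 points in the 2 matched patients. Within antibody panels the smallest possible p of 0.0417 was reached (exact permutation test, 24 assignments, adjusted p = 0.333). Plasma-like cells went the other way (1.97% ± 1.94 against 4.60% ± 2.48, p = 0.143, adjusted p = 0.571, exact permutation test). The other shares differed by less than the spread between tumours (adjusted p = 0.929 for each, exact permutation test). T-like cells made up 50.4% ± 17.2 of metastases and 48.7% ± 24.3 of primary tumours, NK-like cells 3.43% ± 2.40 and 3.25% ± 2.19, and dendritic-like cells 5.68% ± 4.20 and 6.14% ± 2.32. Macrophage-like cells made up 9.76% ± 15.6 and 12.2% ± 7.02, fibroblast-like cells 2.34% ± 2.42 and 3.33% ± 5.54, and epithelial-like cells 3.30% ± 4.25 and 12.2% ± 21.9.

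In T-like cells the lists of naive and of effector states lay apart by site at the preset correlation only, and no gene passed. For naive and central memory, cytotoxic and exhaustion genes adjusted p = 0.118, 0.332 and 0.171 with an estimated correlation. LEF1, a transcription factor of naive T cells (ENSG00000138795, chromosome 4, 108047545 to 108168956, minus strand), had 102 ± 55.3 CPM in metastases and 28.8 ± 7.05 in primary tumours (SD, n = 4 and 5). Its log2 fold change was 1.83 ± 0.32 (edgeR adjusted p = 0.176). CCR7, a chemokine receptor of naive and central memory cells, was at 1.36 ± 0.36. GZMB, the protease granzyme B (ENSG00000100453, chromosome 14, 24630954 to 24634267, minus strand), had 146 ± 108 CPM in metastases against 1107 ± 856 in primary tumours (-2.92 ± 0.80, edgeR adjusted p = 0.328). Perforin, PRF1 (-1.89 ± 0.53), the granule protein GNLY (-2.36 ± 0.83) and the inhibitory receptor LAG3 (51.2 ± 20.02 against 243 ± 166 CPM, -2.26 ± 0.48) lay in the same direction, without overlap between the sites. The sites also differed in T-like clusters. Cluster 2, with LEF1 and KLF2 among its leading genes, held 34.7% of T-like cells in the enzymatic libraries of metastases and 1.39% in those of primary tumours, and 83.4% of it came from the enzymatic library of metastasis 3. Cluster 15, with GZMB, PRF1 and LAG3, held 0.314% and 13.0%. Of its 1184 cells, 761 lay in the enzymatic libraries of primary tumours. As 63.1% of the cluster came from the enzymatic library of primary tumour 5, nearly all of the 13.0% is from that tumour. Levels within clusters were not tested by site.

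By edgeR 0 of 11517 genes passed in T-like cells, with 1074 at an unadjusted p under 0.05 and 89 passing by DESeq2. In all 2.67% of genes had groups that did not overlap against 1.59% by chance. With the antibody panel as a covariate 65 genes passed, among them MS4A1, LEF1, LAG3, GZMB and PRF1. With the patient as a block in limma 45 passed, against 0 in limma without it, and in the mechanical fraction alone 13 passed. All 12 naive and central memory genes lay above 0, of which 0 rose over all genes and 11 adjusted over the list alone. They had a median of 1.05 (camera adjusted p = 9.44e-16; adjusted p = 0.118 with an estimated correlation). Of 16 cytotoxic genes 15 lay below 0, with 0 falling over all genes and 7 falling and 1 rising adjusted over the list alone. Cytotoxic genes had a median of -1.49 (camera adjusted p = 1.16e-09; adjusted p = 0.332 with an estimated correlation). All 14 exhaustion genes lay below 0 (3 fell adjusted over the list alone), with the activation receptor TNFRSF9 at -1.22 ± 0.43. Exhaustion genes had a median of -0.97 (camera adjusted p = 6.14e-08; adjusted p = 0.171 with an estimated correlation). Regulatory T genes had a median of -0.38 (camera adjusted p = 0.0154; adjusted p = 0.649 with an estimated correlation), with the inhibitory receptor CTLA4 at -0.71 ± 0.41. All 10 MHC class II genes lay below 0, 9 falling adjusted over the list alone, with HLA-DRA at 304 ± 90.2 against 686 ± 165 CPM. MHC class II genes had a median of -1.02 (camera adjusted p = 4.26e-13; adjusted p = 0.118 with an estimated correlation). Type I interferon genes, such as ISG15 (-0.83 ± 0.41), had a median of -0.50 (camera adjusted p = 5.67e-06; adjusted p = 0.490 with an estimated correlation). Cell cycle genes had a median of -0.30 (camera adjusted p = 0.0121; adjusted p = 0.649 with an estimated correlation). In both lists 0 genes fell adjusted over the list alone.

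Markers of other cells lay apart by site in T-like cells. MS4A1, the gene of the B cell antigen CD20 (ENSG00000156738, chromosome 11, 60455752 to 60470760, plus strand), had the smallest p, with 15.4 ± 4.55 CPM in metastases against 3.48 ± 0.96 in primary tumours (2.21 ± 0.30, edgeR adjusted p = 0.119). BANK1, a scaffold protein of B cells, was at 2.72 ± 0.45 against 0.24 ± 0.32 CPM (3.07 ± 0.56). Of 8 markers of B cells 7 lay above 0 and 6 rose adjusted over the list alone, with a median of 1.74 (camera adjusted p = 4.35e-12; adjusted p = 0.00766 with an estimated correlation). Naive and memory B genes had a median of 0.62 (4 rose adjusted over the list alone, camera adjusted p = 0.000175; adjusted p = 0.0900 with an estimated correlation). Markers of epithelial cells had a median of -2.37 (camera adjusted p = 0.000754; adjusted p = 0.490 with an estimated correlation). Stress keratins had a median of -2.50, with KRT14 at -3.31 ± 1.48 (camera adjusted p = 1.37e-05; adjusted p = 0.343 with an estimated correlation). Inflammatory monocyte genes had a median of -0.96 (camera adjusted p = 4.60e-07; adjusted p = 0.413 with an estimated correlation) with the myeloid gene S100A8 at -2.50 ± 1.02. Markers of NK cells, macrophages and dendritic cells had medians of -0.72, -0.55 and -0.97 (camera adjusted p = 0.00303, 0.00729 and 0.00762; adjusted p = 0.403, 0.649 and 0.323 with an estimated correlation). Markers of plasma cells and inflammatory fibroblast genes had medians of -0.58 and -0.84 (camera adjusted p = 0.0452 and 0.0178; adjusted p = 0.649 and 0.531 with an estimated correlation). RDH10, a retinol dehydrogenase, also had 1 of the 3 smallest p-values (-2.24 ± 0.35, edgeR adjusted p = 0.176).

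**Figure D3:**
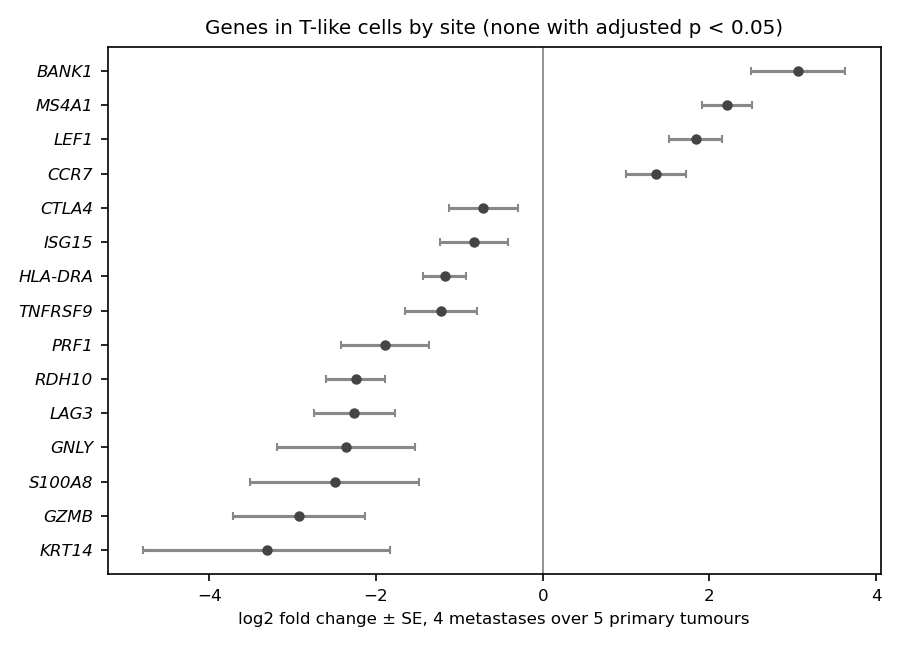
Log2 fold change of metastases over primary tumours with its standard error (horizontal axis) for 15 genes in T-like cells of 4 metastases and 5 primary tumours. Genes of naive T cells and B cells lie above 0 and genes of effector T cells, keratins and S100A8 below 0, from 3.07 for BANK1 to -3.31 for KRT14, and none passed after adjustment.

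In B-like cells the list of naive and memory B genes lay higher in metastases at the preset correlation only, and no gene of it passed. IGHD, the heavy chain of naive B cells, was at 238 ± 104 CPM in metastases and 90.5 ± 75.4 in primary tumours (1.21 ± 0.45). IGHM was at 1728 ± 969 against 985 ± 200 CPM (0.81 ± 0.33) and the memory marker CD27 at 0.81 ± 0.31, and none of the 3 passed (edgeR adjusted p = 0.695 to 0.728). The list had a median of 0.79 with 8 of 11 genes above 0 (camera adjusted p = 0.00270; adjusted p = 0.0599 with an estimated correlation). Immunoglobulin genes had a median of -0.97 with 10 of 11 below 0, and the class-switched constant gene IGHG2 was at -1.60 ± 0.53 (camera adjusted p = 0.00270; adjusted p = 0.173 with an estimated correlation). By edgeR 0 of 2828 genes passed, with 177 at an unadjusted p under 0.05, 13 passing by DESeq2, and 2.05% of genes without overlap against 1.59% by chance. The smallest p-values were those of ANXA4 (-2.38 ± 0.49) and ANXA2 (58.8 ± 21.9 against 179 ± 51.1 CPM, -1.63 ± 0.34), both membrane-binding annexins, and of the ATP-gated channel P2RX5 (1.53 ± 0.33, edgeR adjusted p = 0.207 for the 3). The partial EMT list, here the widely expressed EMP3, ANXA5, LGALS1, ITGB1 and VIM, fell in all 5 members adjusted over the list alone. It had a median of -1.02 (camera adjusted p = 2.91e-06; adjusted p = 0.0599 with an estimated correlation).

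Further lists in B-like cells passed at the preset correlation only. Of 6 inflammatory monocyte genes 4 fell adjusted over the list alone, with a median of -1.82 (camera adjusted p = 1.53e-06; adjusted p = 0.0599 with an estimated correlation). Type I interferon genes had a median of -0.68 (camera adjusted p = 0.00280; adjusted p = 0.442 with an estimated correlation). Heat shock genes had a median of -0.62, with HSPA1B at -2.12 ± 0.78 (camera adjusted p = 0.0158; adjusted p = 0.536 with an estimated correlation). Heat shock and inflammatory monocyte genes also differed between the fractions in B-like cells. The site sums were not adjusted for the unequal numbers of cells from the 2 fractions, so that site and fraction are mixed in these values. MHC class I genes had a median of -0.22 (camera adjusted p = 0.0298; adjusted p = 0.536 with an estimated correlation). Markers of B cells had a median of 0.50 (camera adjusted p = 0.00270; adjusted p = 0.173 with an estimated correlation).

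In macrophage-like cells of metastases the lists of type I interferon and MHC class II genes lay lower at the preset correlation only, and no gene of either passed. HLA-DRA was at 9106 ± 1666 CPM in metastases against 13188 ± 2199 in primary tumours (-0.53 ± 0.21, edgeR adjusted p = 0.865), and all 10 MHC class II genes lay below 0 (median -0.48, camera adjusted p = 0.000104; adjusted p = 0.687 with an estimated correlation). Of 20 type I interferon genes 19 lay below 0, for example the antiviral OAS3 (-1.38 ± 0.46) and IFIT2 (-2.29 ± 0.90). Their median was -0.78 (camera adjusted p = 5.53e-07; adjusted p = 0.687 with an estimated correlation). The peptide transporter TAP2 was at -1.16 ± 0.32 and the MHC class I list at a median of -0.16 (camera adjusted p = 0.0344; adjusted p = 0.732 with an estimated correlation). PTGDS, a prostaglandin D synthase, had 58.0 ± 59.6 against 2.38 ± 2.42 CPM (4.97 ± 0.83). MXI1, an antagonist of MYC, was at 1.79 ± 0.31 (edgeR adjusted p = 0.420 for both), and EML4, a microtubule-binding protein, at -0.90 ± 0.19. By edgeR 0 of 8621 genes passed, with 498 at an unadjusted p under 0.05, 3 passing by DESeq2, and 2.04% of genes without overlap against 1.59% by chance.

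Some lists of other cell types also had medians below 0 in macrophage-like cells, and no gene of them passed over all genes. Markers of epithelial cells had a median of -2.37 (5 of 8 fell adjusted over the list alone, camera adjusted p = 3.54e-05; adjusted p = 0.687 with an estimated correlation). Stress keratins had a median of -2.47 (3 of 6 fell adjusted over the list alone, camera adjusted p = 0.00239; adjusted p = 0.687 with an estimated correlation). KRT17 was at -2.78 ± 1.0 and the collagenase MMP1 at -4.63 ± 1.41. Cytotoxic genes had a median of -1.30 (camera adjusted p = 4.63e-05; adjusted p = 0.687 with an estimated correlation), with GZMB at -2.46 ± 0.84. The lists of exhaustion (2 fell adjusted over the list alone), cell cycle and partial EMT genes had medians of -0.58, -0.69 and -0.16 (camera adjusted p = 0.0436, 0.0441 and 0.0344; adjusted p = 0.687, 0.732 and 0.732 with an estimated correlation).

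In fibroblast-like cells the lists of matrix fibroblast and type I interferon genes lay lower in metastases at the preset correlation only, and no gene passed by edgeR. For these lists adjusted p = 0.581 and 0.344 with an estimated correlation. COL12A1, a collagen of dense matrix, had 119 ± 19.98 CPM in 3 metastases against 483 ± 83.8 in 4 primary tumours (-2.01 ± 0.30). COL11A1 was at -2.46 ± 0.96 and the plasminogen activator PLAU at -1.74 ± 0.33. CYP1B1, a cytochrome P450 (ENSG00000138061, chromosome 2, 38066973 to 38109902, minus strand), had 575 ± 222 against 45.7 ± 25.8 CPM (3.81 ± 0.51). TSPAN11, a tetraspanin (ENSG00000110900, chromosome 12, 30926428 to 30996599, plus strand), had 4.78 ± 0.66 against 37.6 ± 10.8 CPM (-3.06 ± 0.39, edgeR adjusted p = 0.0942 for both). The interferon-induced MX1 was at 13.1 ± 7.88 against 60.9 ± 25.7 CPM (-2.25 ± 0.49) and IFI27 at -1.40 ± 0.36. All 16 type I interferon genes lay below 0, and 6 fell adjusted over the list alone. Interferon genes had a median of -1.21 (camera adjusted p = 9.54e-15; adjusted p = 0.344 with an estimated correlation). By edgeR 0 of 6371 genes passed, with 420 at an unadjusted p under 0.05, 24 passing by DESeq2, and 6.20% of genes without overlap against 5.71% by chance. By limma CYP1B1 and COL12A1 passed with the patient as a block (adjusted p = 0.00903 for both) and without it (adjusted p = 0.0394 for both).

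Among the other lists in fibroblast-like cells, 17 of 21 matrix fibroblast genes lay below 0 (1 fell adjusted over the list alone). Matrix fibroblast genes had a median of -0.36 (camera adjusted p = 0.000271; adjusted p = 0.581 with an estimated correlation). Partial EMT genes had a median of -0.41 (camera adjusted p = 0.000399; adjusted p = 0.523 with an estimated correlation), and MHC class I genes of -0.85 (camera adjusted p = 1.45e-05; adjusted p = 0.523 with an estimated correlation). Inflammatory monocyte genes had a median of -1.67, with the chemokine CXCL8 at -3.41 ± 1.22 (camera adjusted p = 2.35e-05; adjusted p = 0.523 with an estimated correlation). Markers of epithelial cells had a median of -2.32 (camera adjusted p = 1.45e-05; adjusted p = 0.344 with an estimated correlation). Immediate early genes had a median of 0.63 (camera adjusted p = 0.000473; adjusted p = 0.620 with an estimated correlation). Among them were the transcription factor KLF4 at 2.79 ± 0.81 and the antiproliferative BTG2 at 2.92 ± 0.91. The fraction was not tested in fibroblast-like cells, and the site sums were not adjusted for the unequal numbers of cells from the 2 fractions.

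Epithelial-like cells were compared in 3 metastases and 3 primary tumours. INHBA, the activin A subunit (ENSG00000122641, chromosome 7, 41667168 to 41705834, minus strand), was at 3.15 ± 4.13 against 91.1 ± 90.2 CPM (-5.59 ± 1.63), MMP1 at -4.10 ± 1.91 and GBP1, an interferon-induced GTPase, at -2.57 ± 0.71. From the list of lymph node stroma FDCSP, a product of follicular dendritic cells that was also among the leading genes of an epithelial-like cluster at resolution 2, was at 373 ± 323 against 14.9 ± 25.8 CPM (4.57 ± 2.09). The chemokine CCL19 was at 17.1 ± 11.1 against 2.09 ± 2.26 CPM (3.73 ± 0.96). LINC01116 was at 49.0 against 11.2 CPM (2.14 ± 0.51), and the mitotic cyclin CCNB1 at -1.57 ± 0.62. The ammonium transporter RHCG of differentiated squamous cells was at -2.83 ± 1.42 and HLA-F at -1.73 ± 0.67. None passed (edgeR adjusted p = 1 for each gene). By edgeR 0 of 8494 genes passed, with 73 at an unadjusted p under 0.05, 0 passing by DESeq2, and 5.66% of genes without overlap against 10% by chance. Simulated 4-fold changes were not found at this size.

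Lists in epithelial-like cells passed at the preset correlation alone. Of 31 partial EMT genes 30 lay below 0, with a median of -0.86 (camera adjusted p = 1.13e-07; adjusted p = 0.374 with an estimated correlation). MHC class I genes had a median of -1.05 (camera adjusted p = 6.86e-05; adjusted p = 0.512 with an estimated correlation), and inflammatory monocyte genes of -1.15 (camera adjusted p = 8.62e-06; adjusted p = 0.374 with an estimated correlation). Inflammatory fibroblast genes had a median of -1.32 (camera adjusted p = 0.00462; adjusted p = 0.374 with an estimated correlation), and matrix fibroblast genes of -1.26 (camera adjusted p = 0.00259; adjusted p = 0.545 with an estimated correlation). Stress keratins and squamous differentiation genes had medians of -0.54 and -0.50 (camera adjusted p = 0.00259 and 0.0252; adjusted p = 0.732 for both with an estimated correlation). Cell cycle genes and fibroblast markers had medians of -0.33 and -1.07 (camera adjusted p = 0.0349 and 0.0199; adjusted p = 0.374 and 0.732 with an estimated correlation). Of 5 lymph node stroma genes 4 lay above 0, with 0 rising over all genes and 1 adjusted over the list alone (median 2.53, camera adjusted p = 0.000403; adjusted p = 0.374 with an estimated correlation). Immunoglobulin genes had a median of 0.30 (camera adjusted p = 0.00719; adjusted p = 0.732 with an estimated correlation).

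By site, 0 of the shared antibodies passed (0 in T-like, B-like and macrophage-like cells by edgeR, 3 metastases against 3 primary tumours). CD8 in T-like cells was at 386 ± 244 molecules per cell in metastases against 774 ± 129 (-0.93 ± 0.30, edgeR adjusted p = 0.159). CD3 was at -0.59 ± 0.34 (edgeR adjusted p = 0.358) and CD4 at 0.07 ± 0.33.

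The third comparison tested whether the effect of dissociation depended on the site. In T-like cells the log2 fold change of enzymatic over mechanical was higher in metastases by 1.45 ± 0.28 for FOSL2, an AP-1 component (ENSG00000075426, chromosome 2, 28392448 to 28417312, plus strand). For LRMP it was lower in metastases (-1.13 ± 0.22). Such a term does not tell whether a gene rises or falls at either site. They were among the 3 smallest p-values, and no gene passed (edgeR adjusted p = 0.313 for both). Of 22 cell cycle genes 20 lay above 0 and 5 rose adjusted over the list alone, with a median of 0.60 (camera adjusted p = 5.79e-15; adjusted p = 0.490 with an estimated correlation). Regulatory T genes had a median of 0.49 (camera adjusted p = 0.000131; adjusted p = 0.582 with an estimated correlation). Of 17 markers of macrophages 16 lay above 0, with a median of 0.93 (camera adjusted p = 4.73e-05; adjusted p = 0.651 with an estimated correlation). In macrophage-like cells all 18 inflammatory monocyte genes lay above 0 (0 rose over all genes and 2 rose adjusted over the list alone, median 1.47, camera adjusted p = 3.59e-07; adjusted p = 0.230 with an estimated correlation). Of 10 markers of T cells 9 lay above 0 (median 1.43, camera adjusted p = 0.000402; adjusted p = 0.252 with an estimated correlation). Hypoxia and heat shock genes had medians of -0.44 and -0.52 (camera adjusted p = 0.000196 and 0.000458; adjusted p = 0.354 for both with an estimated correlation).

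The genes with the smallest p in macrophage-like cells were PHB (-1.17 ± 0.29), LMNA (1.74 ± 0.45), the gene of nuclear lamin A, and ANGPTL4 (-2.35 ± 0.59, edgeR adjusted p = 0.885 for the 3). By edgeR 0 genes passed in T-like cells (of 10957, 522 at an unadjusted p under 0.05) and 0 in macrophage-like cells (of 5686, 301 at an unadjusted p under 0.05), and DESeq2 was not run for this term. With no filter on low counts 47 and 27 genes passed. In shares, the difference between the fractions was -6.97 ± 6.11 points for B-like cells in metastases (n = 4) and -0.131 ± 1.39 in primary tumours (n = 5, exact two-sided permutation test, p = 0.0317, adjusted p = 0.159). In primary tumours B-like cells made up only 1.30% and 1.43% of the 2 fractions, so that the base level largely sets this comparison in points. For dendritic-like cells the margin was smaller in metastases (-1.40 ± 1.02 against -4.73 ± 2.64, p = 0.0397, adjusted p = 0.159, exact permutation test). Neither passed after adjustment.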

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

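The test of antibody depth for CD185 and the splits of the samples, apart from those of NK-like, dendritic-like and plasma-like cells, were tests chosen after the result had been seen.

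Most immediate early and heat shock genes were higher in the enzymatic fraction of all 6 classes tested. The lists lost their call in B-like (adjusted p = 0.0768 with an estimated correlation) and macrophage-like cells (adjusted p = 0.0780 with an estimated correlation). For depth, the summed UMIs of T-like cells were thinned within each tumour to the smaller total of its 2 fractions. The median log2 fold change of the 36 genes was then 2.18 against 2.19 (ratio 0.997), with 1829 in place of 2022 genes passing. Random thinning of sums keeps the expected proportions of genes, so that an unchanged median was fixed in advance. A difference in depth per cell was not tested by this and stays open. Against free RNA from other cells, the summed level of these genes in T-like cells of enzymatic libraries was not lower than in all other cells (median ratio 1.112, range 0.849 to 1.675 over 9 tumours, with 18919 against 15387 CPM). Against a selection of cells particular to the T-like class, the lowest median in NK-like, dendritic-like and plasma-like cells was still 1.859. Open remain a response of the cells to the enzymatic step, to its temperature or to its duration, which the labels do not separate, so that a dissociation response is a hypothesis these values may reflect, and a selection of cells that acts on all classes alike.

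CD185 antibody signal was lower in the enzymatic fraction of B-like cells (fitted log2 fold change -6.18). A lower transcript level is argued against by CXCR5 RNA, which was higher by 1.0319. A lower antibody depth in the enzymatic fraction is argued against by the other 15 shared antibodies, whose median log2 ratio per cell was 0.151 (range -0.896 to 1.389) against -6.265 for CD185. Loss of the epitope to the enzymes is a hypothesis that could account for it, and no labelled sample with enzyme added to mechanically dissociated cells was analysed here to test it. A difference in staining between the fractions that is particular to this antibody also stays open.

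B cell genes were higher in T-like cells of metastases, where B-like cells were also more frequent. Free RNA from B cells is a candidate source, since 13 of 15 B markers (86.667%) had a ratio of the level in T-like cells to that in B-like cells within 2-fold of the median ratio of 1.5% (range 0.812% to 8.41%), as a single source would give. B cells joined to T-like cells in one droplet cannot be told apart from this, since MS4A1 and CD79A were detected together in T-like cells 2.154 times as often as independent detection would give (range 1.485 to 7.612 over metastases), which differences in depth between cells also raise. MS4A1 had a UMI in 1.97% to 4.91% of T-like cells in metastases and in 0.504% to 1.32% in primary tumours. A difference in the T cells of lymph nodes themselves was not tested and stays open.

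A tumour far from the others of its group was found in 20 of 188 groups, 8 of shares, 12 of genes and 0 of antibodies, and chance gives about 1 in 20. Each value is followed by the range of the other tumours. Epithelial-like cells made up 61.7% of 1 mechanical library of primary tumours (0.0678% to 2.41%) and 14.2% of 1 mechanical library of metastases (0% to 1.37%). Fibroblast-like cells made up 19.6% of 1 enzymatic library of primary tumours (0.556% to 2.61%), 6.87% of 1 mechanical library of primary tumours (0.0675% to 0.431%) and 2.88% of 1 mechanical library of metastases (0% to 0.0577%). Macrophage-like cells made up 29.2% of 1 enzymatic (1.02% to 5.73%) and 36.8% of 1 mechanical library of metastases (0.619% to 2.88%), and NK-like cells 6.63% of 1 enzymatic library of primary tumours (1.24% to 2.80%).

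Among log2 ratios of the enzymatic to the mechanical fraction, 1 tumour stood apart in T-like cells for NR4A2 at 9.34 (3.85 to 5.88), GEM at 7.63 (3.31 to 4.62) and GIMAP6 at -2.13 (-1.11 to -0.47), in B-like cells for MT-ND6 at -5.72 (-1.68 to -0.73), and in macrophage-like cells for GEM at 0.16 (3.23 to 5.39), TNF at 6.70 (2.50 to 4.34) and CCL4 at 9.93 (0.49 to 5.24). Among log2 CPM values, 1 primary tumour stood apart for MS4A1 in T-like cells at 1.09 (1.87 to 2.18), ANXA4 and IGHG2 in B-like cells, both at -0.10 (5.82 to 6.37 and 6.37 to 8.27), and CXCL8 in fibroblast-like cells at 6.0 (11.86 to 12.31), and 1 metastasis for KRT17 in macrophage-like cells at 0.32 (3.46 to 4.08). Outside the comparisons, 52 antibodies that were in 1 or 2 of the panels had more than 3 molecules in all.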

How the results depend on the processing

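The alternatives with unnamed cells as T-like, without small libraries and without single tumours for the interaction, and limma without the block, were tests chosen after the result had been seen. Of 63 fraction genes named, 968 values under alternatives gave 925 on the same side of the threshold, 43 weaker and 0 reversed, and of 52 site genes 942 values gave 886 the same and 56 stronger; of 5 interaction genes, 55 values gave 51 the same and 4 stronger. For the 8 antibodies that passed, 28 of 62 values stayed past the threshold and 34 did not, 8 of them in the exact sign-flip test, whose smallest p left almost no room to pass; CD185 in B-like cells passed with the other scaling, without the block and without each tumour. No called gene changed direction in any setting. For changes below, the cause was not tested, except that fewer tumours or an unpaired fit lower the power by construction. Whether depth limits the classes with few cells was not tested.

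Fraction shares: on the log2 odds scale T-like cells had 0.0536 and epithelial-like cells 0.652, both with the sign turned. At resolution 0.5 the dendritic-like difference was -0.324 (1 class passing), at resolution 2 it was -1.30 and the macrophage-like one -5.16 and passing. With no replicate block (pairing left out) the differences of -3.25 and 3.45 did not pass (0 classes), nor did -2.76 and 1.53 without the tumours with a library under 500 cells (0 classes). Counting unnamed cells as T-like gave 3.07 for T-like cells. Leaving out 1 tumour at a time turned the sign for T-like (-2.88 to 1.82) and epithelial-like cells (-2.76 to 1.10). The other classes kept their sign but varied in size, for example -0.958 to -0.064 for NK-like and 0.103 to 1.54 for plasma-like cells.

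Site shares: the dendritic-like difference turned to 0.531 at resolution 0.5, 1.21 in the enzymatic fraction alone and 0.75 without the small libraries, where the fibroblast-like one turned to 0.987. The T-like one turned to -2.75 in the mechanical fraction alone and -1.81 with unnamed cells counted. In the pairing by patient (replicate block of the 2 matched patients, no test) the plasma-like one was 0.357 and the dendritic-like one 0.702, both with the sign turned. The T-like one was 13.5 (16.5 and 10.6 in the pairs) against 1.74 over all tumours. The NK-like one was 1.26 against 0.181 and the epithelial-like one -22.9 against -8.89. Leaving out 1 tumour gave -0.802 to 1.09 for NK-like, -7.105 to 8.61 for T-like, -2.27 to 1.11 for dendritic-like, -11.9 to 0.826 for epithelial-like, -1.87 to 1.47 for fibroblast-like and -10.1 to 0.591 for macrophage-like cells; B-like cells stayed higher in metastases (13.8 to 21.8).

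Fraction expression: with no replicate block (no pairing) 780 genes passed in T-like, 276 in B-like and 191 in macrophage-like cells, and with no filter 857 in macrophage-like cells. Without single tumours 312 to 618 passed in B-like cells, the lowest without metastasis 4. With the correlation estimated, 3 of 6 lists in T-like cells and 0 of the 4 in B-like and the 7 in macrophage-like cells passed, 1 of 17 in T-like cells for the site and 0 in epithelial-like (11), B-like (8), macrophage-like (9) and fibroblast-like cells (7), and 0 of 10 and 11 for the interaction.

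Site expression: in T-like cells 4 genes passed with no filter, 89 with DESeq2, 45 with the patient as replicate block, 65 with the panel as covariate and 13 in the mechanical fraction alone. In B-like cells these were 86 with no filter, 13 with DESeq2, 3 with the block and 2 in limma without it, in macrophage-like cells 3, 3 and 4 with no filter, DESeq2 and the block, and in fibroblast-like cells 95, 24, 2 and 2. Without single tumours 0 to 3 passed in B-like, 0 to 1 in macrophage-like and 0 to 4 in fibroblast-like cells. The interaction had 47 genes in T-like and 27 in macrophage-like cells with no filter, and 0 to 1 in both without single tumours.

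Antibodies, fraction: scaling to the total gave 0 in T-like and 3 in B-like cells, the exact sign-flip test 0, 0 and 0 in the 3 classes, and no replicate block 0 in T-like and 2 in B-like cells. Without single tumours 0 to 3 passed in T-like, 2 to 5 in B-like and 0 to 1 in macrophage-like cells, and CD3 in T-like cells ranged from -0.0426 (without primary tumour 2) to 0.455. For the site, 0 to 4 passed in T-like and 0 to 1 in macrophage-like cells.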

Other observations

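The fits of NK-like, dendritic-like and plasma-like cells were tests chosen after the first results had been seen. In NK-like cells of 6 tumours NR4A1 was higher in the enzymatic fraction by 5.81 ± 0.31 on the log2 scale (edgeR adjusted p = 1.38e-09) and DNAJB1 by 4.95 ± 0.29, while S1PR4, a receptor of sphingosine 1-phosphate, fell by 1.4 ± 0.23 and CXCR6, a chemokine receptor of tissue-resident lymphocytes, fell by 1.30 ± 0.35. By edgeR 335 of 2695 genes passed (259 higher, 76 lower). All 17 immediate early and 11 heat shock genes rose, with medians of 3.10 and 2.64 (adjusted p = 0.0127 and 0.010 with an estimated correlation). In dendritic-like cells of 8 tumours 322 of 4959 genes passed by edgeR (268 higher, 54 lower). HSPA1B (4.66 ± 0.58), the chemokine CXCL2 (4.46 ± 0.44) and HES1, a target of Notch (4.21 ± 0.45), were among the 5 largest increases. Of 20 immediate early genes 18 rose (median 1.91; adjusted p = 0.0131 with an estimated correlation), of 13 heat shock genes 13 (median 1.51; adjusted p = 0.0330 with an estimated correlation) and of 13 inflammatory monocyte genes 8, or 11 adjusted over the list alone (median 1.85; adjusted p = 0.0330 with an estimated correlation). In plasma-like cells of 5 tumours 231 of 3486 genes passed by edgeR (180 higher, 51 lower), with HSPA1B higher by 5.49 ± 0.28 and 16 of 17 immediate early (median 2.49) and 11 of 12 heat shock genes (median 2.32) rising (adjusted p = 0.0300 for both with an estimated correlation). Among the lower genes of plasma-like cells were MYBL2 (-1.34 ± 0.32), the histone gene HIST1H4C (-1.32 ± 0.22) and PCLAF (-1.12 ± 0.30). The cell cycle list had a median of -0.80, with 1 of 12 members falling over all genes (camera adjusted p = 3.26e-06; adjusted p = 0.364 with an estimated correlation).

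The antibodies against CD326 and CD45, each in 2 of the panels, differed between epithelial-like and T-like cells. In the enzymatic library of metastasis 4, epithelial-like cells carried 676 molecules of the CD326 (EPCAM) antibody per cell against 19.1 in T-like cells, and 469 of the CD45 antibody against 3293. In that of primary tumour 5 these were 181 against 18.7 for CD326 and 218 against 1425 for CD45. The CD56 antibody (NCAM1), which all panels held, varied widely between libraries. Epithelial-like cells had 805 molecules per cell in the enzymatic and 5664 in the mechanical library of primary tumour 2. In metastasis 1, from the same patient and with the same panel, these were 123 and 6219. The enzymatic libraries of metastasis 4 and primary tumour 5, from other patients, had 21.2 and 53.2. These are values of single libraries without a test.

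Counts of passing genes were set against other splits of the samples, the real one included. For the fraction, the real split gave the highest count in 1 of 100 splits for T-like cells (2022 against 1369 for the next highest, which exchanged the fractions of metastasis 1), macrophage-like cells (462 against 240) and dendritic-like cells (322 against 128), and in 1 of 32 for NK-like cells (335 against 0), so that chance was excluded at 0.05. For B-like cells (524 against 60) and plasma-like cells (231 against 10) the 16 splits are too few for a share under 0.05. For the antibodies 1 of 32 splits gave as many as the 1 in macrophage-like cells (highest other 0), 2 of 32 as many as the 2 in T-like cells (highest other 2), where chance was not excluded, and the 8 splits of B-like cells (5 against 0) are too few.

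For the site the real split gave 0 genes by edgeR, which every split reaches by construction (100 of 100 in T-like, B-like and macrophage-like cells and 35 of 35 in fibroblast-like cells), so that the splits do not bear on chance here. The highest other counts were 8 in T-like, 9 in B-like, 8 in macrophage-like and 5 in fibroblast-like cells. The counts at an unadjusted p under 0.05 and by DESeq2 were 1074 and 89, 177 and 13, 498 and 3, and 420 and 24. For the interaction the real split gave 0 genes too, so that its 100 splits do not bear on chance either (highest others 15 in T-like and 4 in macrophage-like cells), with 522 and 301 genes at an unadjusted p under 0.05. The 10 splits of epithelial-like cells are too few, with 0 genes against 363 in another split (73 at an unadjusted p under 0.05 and 0 by DESeq2). That split put metastases 1 and 4 and primary tumour 2 together, against metastasis 2 and primary tumours 3 and 5. It thus kept both tumours of each of the 2 matched patients on the same side, and the reason for its count was not tested. The 10 splits of the antibodies by site are too few as well (0 against 0, 1 and 1 in T-like, B-like and macrophage-like cells).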
